A study of Danio rerio with 18 samples.

How the data were processed

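The series holds 18 libraries, each from 1 whole zebrafish larva, in 4 groups given by the labels: resilient or susceptible archetype, basal or stressed. Per the labels' protocols, larvae were sorted at 6 dpf, rested for a day and collected at 7 dpf into Trizol, some without a stress and others 30 min after a stress of 5 min. RNA was isolated by phase separation and libraries followed standard Illumina protocols, per the labels' protocols. The series' design text speaks of 5 biological replicates; the basal groups hold 4 larvae each in the samples used here. How larvae were scored as resilient or susceptible, and which clutches or days they came from, is not given in the sources used here.

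The authors deposited raw counts of reads per gene symbol, per the file headers. Per the submitters' processing notes, cutadapt, STAR, DESeq2 and the danRer11 build were used, with versions and order not given in the sources used here. The gene counter, annotation and strand setting are not given in the sources used here, so overlapping genes and antisense partners cannot be separated. The same table holds size-factor scaled counts (a signal scale), regularized log2 values, log2 fold changes, p-values and adjusted p-values that the authors deposited, per the file headers. These deposited p-values and log2 fold changes were used only for the counts quoted from the authors' deposited table. Of 25281 rows, 15 carry a name that a spreadsheet had turned into a date. These rows name no gene and were left out of library sizes and tests, and they held 0.0613% to 0.0698% of each library's reads.

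Total counts over all rows ranged from 8452595 to 23801175 reads per library. All comparisons came from 1 fit over the 18 libraries with 4 group means, by edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, robust quasi-likelihood dispersion and the quasi-likelihood F test. That left 22038 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. SE is the absolute log2 fold change over the square root of F. Log2 CPM for principal components used a prior count of 2. Each larva is a separate animal, so edgeR p-values of single genes measure the spread between larvae.

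The 7 comparisons, their tests, the alternatives listed first below, 38 gene lists and the rule for named genes were fixed before the data were examined. Of 1350 list entries 1147 matched a row by symbol, by an older symbol in the RefSeq gene table of assembly GRCz12tu (names and neighbours only) or by a single numbered copy, and 1094 were tested. Lists with at least 5 tested members were tested, which left 36; vitellogenins and mitochondrially encoded genes had 0 tested members. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 36 lists of a comparison. With the correlation estimated per list, no list was called in any comparison. For stress in resilient larvae the estimates ran from -0.014 for monoamine neurons to 0.846 for cell proliferation, with 0.431 for complement. The preset treats the genes of a list as nearly independent. Where genes move together, camera p-values with the preset therefore do not measure the spread between larvae and may be far too small. Named genes had an assigned symbol and a mean of at least 1 CPM. Per comparison they were taken from the 10 called genes with the smallest p in each direction, from up to 4 called members per list (2 where over 8 lists had calls), from the 3 smallest p not called where under 5 were called, and from a fixed panel of stress and complement genes. c6, of the panel, is named although its mean lay below 1 CPM. Fewer were named than the rule takes. Values of 3 further genes are not reported here.

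The steps were tested on simulated data in which 200 of the real genes were changed. Each gene was drawn independently there, without variation shared by many genes within a larva, so recovery in the real larvae may be lower. A count of 0 called genes therefore does not show that no gene changed. For the stress response of resilient larvae, run on 21867 genes, 35.8% of genes changed by 0.5 on the log2 scale were recovered, 65.7% of those changed by 1 and 95.5% of those changed by 2. For the susceptible stress response, run on 21842 genes, the shares were 23.9%, 80.6% and 90.9%. For the basal archetype comparison, run on 21856 genes, they were 23.9%, 61.2% and 90.9%. For the archetypes after stress, run on 21858 genes, they were 29.9%, 85.1% and 93.9%, and for the difference of responses, run on 21856 genes, 8.96%, 50.75% and 83.3%. Larval pairs of 1 group were compared for identical libraries: over 32 pairs, chi-square per degree of freedom was at least 8.09, so none agreed within sampling noise.

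Alternatives fixed beforehand were DESeq2 1.42.0, voom with sample quality weights, RLE and upper-quartile factors, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, a fit of only the groups compared, a replicate block by the number in the title or in brackets, an absolute log2 fold change of at least 1, 1 surrogate variable (sva 3.50.0), and leaving out each larva. Alternatives chosen after seeing the data were leaving out resilient stressed 2 and 3, leaving out susceptible basal 1 and 2, leaving out resilient basal 1 and 3, leaving out the larvae whose copy shares lay between the modes, and summing numbered copies. The rule that picked the latter larvae (over double the median percentage of pairs between the modes) was written after copy shares had been looked at, and it took 4 larvae, where 3 had been picked by eye; 19 pairs in 11 regions bear on it, which are not independent. Reads of a gene and its numbered copy may be split by the counting, so the counts of srgn, tln2a and ubb, which have such a copy, are uncertain, and tsc22d3 is not reported. As a test of library size, all libraries were also thinned to the lowest total.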

Results

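Whole-larva RNA was sequenced from 18 zebrafish larvae of the AB strain, 1 larva per library. Larvae had been separated into a resilient and a susceptible archetype at 6 days post fertilization (dpf) and were taken at 7 dpf, either without a stress (basal) or 30 min after a stress that lasted 5 min. The groups held 4 resilient basal, 5 resilient stressed, 4 susceptible basal and 5 susceptible stressed larvae. Raw read counts summed to between 8452595 and 23801175 per larva, and 22038 genes had enough reads to be tested. Levels are given in CPM (counts scaled to library size) as mean ± SD over the larvae of a group. Values in parentheses after a gene are its log2 fold change with standard error (SE) and adjusted p from edgeR.

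The first principal component of log2 CPM held 17.3% of the variance, and the 5 resilient stressed larvae scored between 16.6 and 57.0 on it, while the other 13 larvae scored between -34.5 and 3.92. Resilient stressed larvae 2 and 3 had the highest scores, 53.7 and 57.0.

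**Figure D1:**
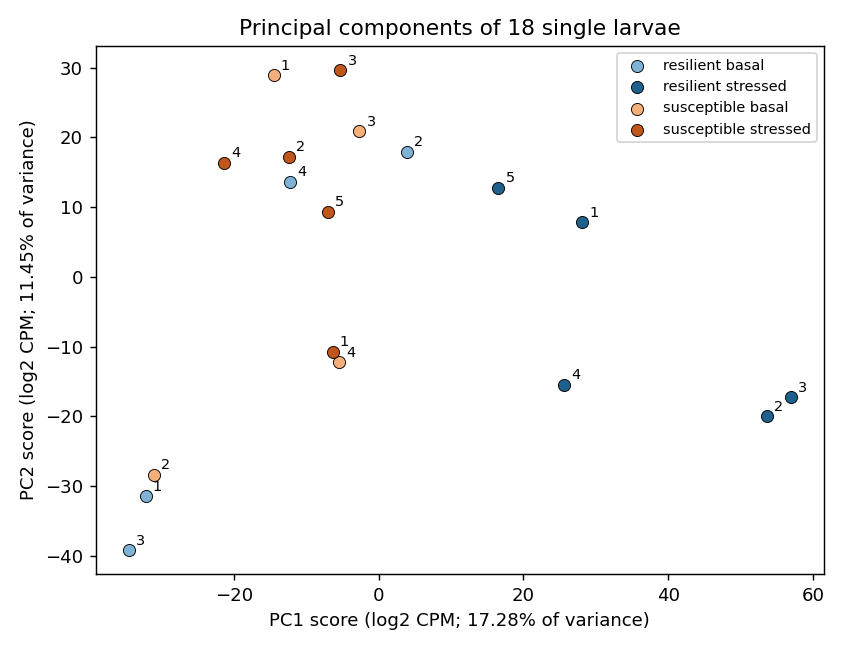
Scores of the 18 larvae on the first (x axis, 17.28% of variance) and second (y axis, 11.45% of variance) principal components of log2 CPM, each point being 1 larva with its replicate number. All 5 resilient stressed larvae lie at first-component scores of 16.6 or more, to the right of the other 13 larvae.

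The first comparison asked how stressed resilient larvae differed from basal ones. These are different larvae of unknown clutch and day, so a difference present before the stress cannot be separated from a response to it. Here and below, a gene that rose or fell was higher or lower in stressed than in basal larvae. In resilient larvae, 16 of 39 genes of the complement system, the plasma proteins and receptors that tag and lyse targets, were called lower after stress. The series title names complement factors, so this list was chosen with the study's own result in view and its direction is not independent evidence. The terminal pathway gene c7a went from 38.5 ± 2.56 CPM (n = 4) to 12.4 ± 3.01 CPM (n = 5), with log2 fold change -1.64, SE 0.19, adjusted p = 0.000506. Of the 39 members of the complement list, 16 were called lower and 0 higher over all genes tested, and 29 lower when adjusted over the list alone. The median log2 fold change of the list was -0.995 (camera adjusted p = 6.99e-17, adjusted p = 0.475 with an estimated correlation). List scores (mean centred log2 CPM) were 0.460, -0.140, 0.871 and 0.326 in resilient basal 1 to 4. Resilient stressed larvae scored -1.029 to -0.213, so resilient basal 2 lay close to the highest of them. Called members included clu, which encodes the complement-binding chaperone clusterin, at -0.58 (SE 0.09), the component genes c5 at -1.26 (SE 0.29), c8a at -0.995 (SE 0.25) and c9 at -1.52 (SE 0.38), the convertase gene cfb at -1.69 (SE 0.40) and the lectin-pathway protease gene masp2 at -1.01 (SE 0.27). The 3 measured c3a genes had log2 fold changes of -1.16 (SE 0.43), -2.38 (SE 0.69) and -1.58 (SE 0.51) and did not pass the test (adjusted p = 0.123, 0.0532 and 0.0789 for c3a.1, c3a.2 and c3a.3). These c3a genes are closely related copies, so the split of reads among them is uncertain. masp1 was at -0.08 (SE 0.12) with adjusted p = 0.764.

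**Figure D2:**
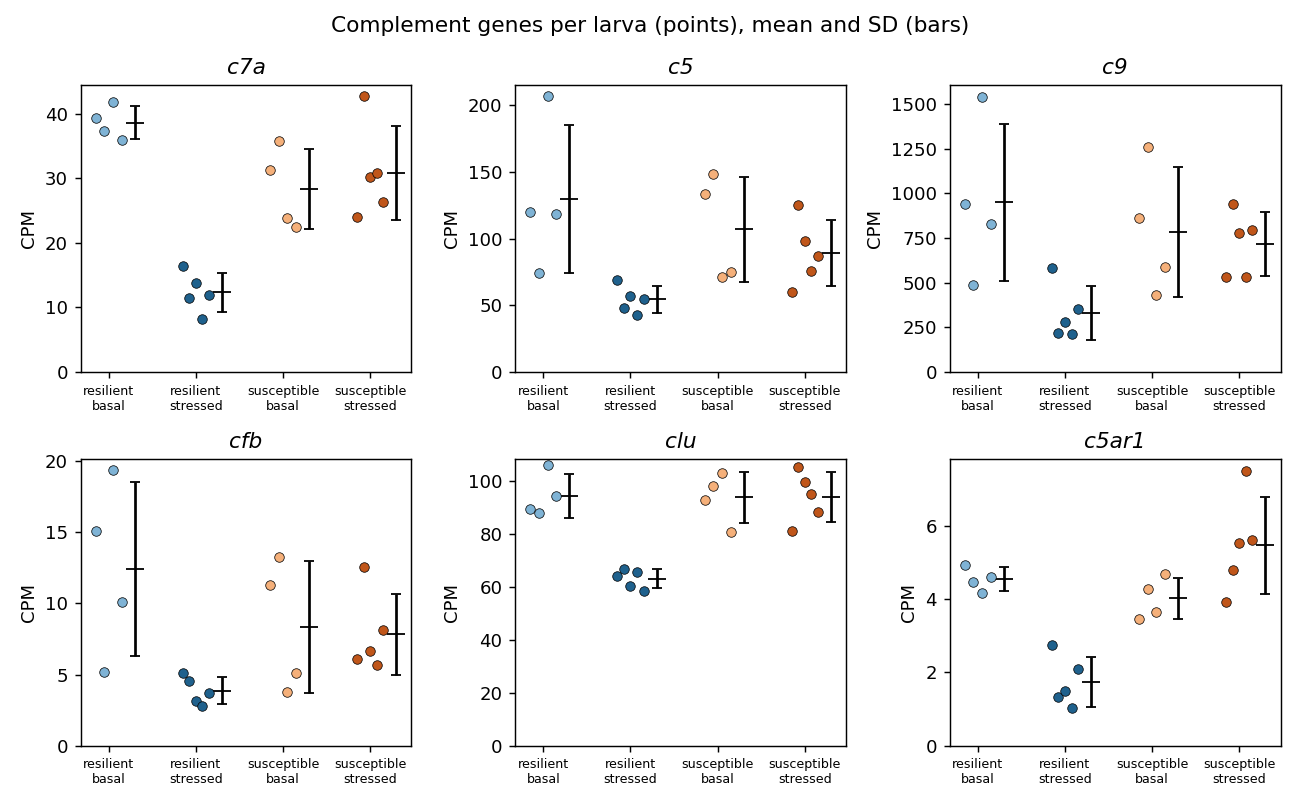
CPM (y axis, linear from 0) of 6 complement genes in each larva (points) of the 4 groups (x axis), with the group mean and SD as bars. For c7a the 5 resilient stressed larvae averaged 12.4 CPM, against 38.5 CPM in resilient basal larvae and 30.8 CPM in susceptible stressed larvae.

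The interleukin 6 family receptor gene il6st (-0.66, SE 0.07, adjusted p = 0.000506), the transcription factor gene stat3 (-0.65, SE 0.08, adjusted p = 0.000783) and socs3b, a feedback inhibitor of that pathway (-0.76, SE 0.12, adjusted p = 0.00269), fell in resilient larvae. The list of inflammatory cytokines and NF-kB targets had 6 of 28 members lower and 2 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.0149, adjusted p = 0.475 with an estimated correlation; camera adjusted p = 0.142 without resilient basal 1 and 3). Of 19 macrophage and microglia markers, 8 were lower and 0 higher (12 lower and 2 higher adjusted over the list alone), including mpeg1.2 at -1.89 (SE 0.35) and the protease gene ctss2.1 at -1.19 (SE 0.23); the list gave camera adjusted p = 5.69e-06, adjusted p = 0.478 with an estimated correlation. Of 14 neutrophil markers 3 were lower (6 adjusted over the list alone), among them srgn at -1.39 (SE 0.24), which has a numbered copy that makes its count uncertain (camera adjusted p = 1.19e-05, adjusted p = 0.486 with an estimated correlation). Resilient basal 1 and 3 stood apart on this list, with scores (mean centred log2 CPM) of 0.783 and 0.734 against -0.234 and -0.030 in resilient basal 2 and 4 and -0.754 to -0.054 in stressed larvae; without them camera adjusted p = 0.029. The coagulation list had 7 of 16 members lower (10 adjusted over the list alone), with a2ml at -0.76 (SE 0.17) and f7 at -0.58 (SE 0.15) (camera adjusted p = 1.59e-06, adjusted p = 0.478 with an estimated correlation). Among 32 acute phase and secreted liver proteins, 7 were lower and 1 higher (15 and 2 adjusted over the list alone), with itih3a at -0.59 (SE 0.11) (camera adjusted p = 0.000231, adjusted p = 0.486 with an estimated correlation). Resilient basal 3 stood apart on this list at 0.594. The other resilient basal larvae scored -0.2255 to 0.0677, which overlaps the -0.4139 to -0.1295 of resilient stressed larvae.

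Some chaperone genes were lower too. The unfolded protein response list had 13 of 28 members lower and 1 higher (16 and 3 adjusted over the list alone), including canx at -0.66 (SE 0.11) and dnajc3b at -0.79 (SE 0.14) (camera adjusted p = 3.76e-06, adjusted p = 0.486 with an estimated correlation). Its members did not all move one way, with 21 negative and 7 positive. The member chac1 averaged 471 ± 112 CPM in resilient basal and 728 ± 166 CPM in resilient stressed larvae. On this list too resilient basal 1 and 3 stood apart, at 0.313 and 0.481 against -0.038 and 0.123 in the other basal larvae and -0.304 to -0.040 in stressed larvae; without them camera adjusted p = 0.00493. The heat shock list had 6 of 25 members lower (13 adjusted over the list alone), led by the small heat shock gene hspb1 (-1.503, SE 0.20, adjusted p = 0.0013), with camera adjusted p = 6.08e-07, adjusted p = 0.475 with an estimated correlation. Resilient basal 1 and 3 scored highest on it, at 0.299 and 0.400 against 0.0907 and 0.0515 in resilient basal 2 and 4. Resilient stressed larvae scored lower than all of these, at -0.324 to -0.1538. The metalloproteinase inhibitor gene timp2b (-1.73, SE 0.20, adjusted p = 0.000726), the protease gene adamts1 (-1.19, SE 0.16, adjusted p = 0.00151) and the membrane repair gene dysf (-1.06, SE 0.14, adjusted p = 0.00112) were also lower. Of 43 cell proliferation genes 2 were lower (3 adjusted over the list alone), one being the replication helicase gene mcm4 at -0.80 (SE 0.21) (camera adjusted p = 2.38e-11, adjusted p = 0.647 with an estimated correlation). Resilient stressed 2 and 3 stood apart on this list, with scores (mean centred log2 CPM) of -0.969 and -1.020, while resilient stressed 5 scored 0.459 and the basal larvae -0.139 to 0.604; without larvae 2 and 3 camera adjusted p = 0.000347.

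Of 33 immediate early genes, which are transcribed within minutes of cell stimulation, 7 rose in resilient larvae and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0121, adjusted p = 0.647 with an estimated correlation). egr1 rose from 28.9 ± 3.197 CPM to 65.04 ± 16.0 CPM (1.18, SE 0.18, adjusted p = 0.00281), ier2a by 1.45 (SE 0.23), fosab by 1.94 (SE 0.47) and the neuronal activity gene npas4a by 0.71 (SE 0.18) on the log2 scale. crhb, which encodes corticotropin-releasing hormone at the head of the stress axis, rose by 0.63 (SE 0.14) (adjusted p = 0.0135). Further genes that rose were the forkhead gene foxq1a (2.1996, SE 0.31, adjusted p = 0.00217) and asb10 (1.48, SE 0.20, adjusted p = 0.0013). So did pfkfb1, an enzyme gene of glycolytic control (0.83, SE 0.12, adjusted p = 0.0016), fbxo32, a ubiquitin ligase gene of muscle protein breakdown (1.65, SE 0.32, adjusted p = 0.00964), and the prostaglandin synthase gene ptgs2b (1.74, SE 0.34, adjusted p = 0.00971).

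In all, 1399 genes were called between stressed and basal resilient larvae, 608 higher and 791 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Without resilient basal 1 and 3 the count was 38, with the complement list called lower (camera adjusted p = 1.54e-11). Without resilient stressed larvae 2 and 3 the count was 69. All 1399 genes kept their sign there, with a median ratio of fold changes of 0.8645, in fits that share the other larvae. With 1 surrogate variable the count was 10, with a replicate block by title or bracket number 863 and 430, in a fit of these groups alone 640, and with an absolute log2 fold change of at least 1 it was 284. It fell to 398, 675, 790, 601 and 604 when resilient basal 1, 3 or 4 or resilient stressed 2 or 3 was left out alone. The calls of c7a, clu, il6st, stat3, egr1 and ier2a held with any 1 larva left out, whereas others did not. Those of c5, c8a, c9, cfb, masp2, a2ml, f7, mcm4, fosab and npas4a ended without resilient basal 1 and without resilient basal 3, and each also without 1 to 4 further single larvae among resilient basal 2 and 4 and resilient stressed 1 to 4 (adjusted p up to 0.133). That of crhb ended without resilient basal 1 alone (adjusted p = 0.0564). The call of the immediate early list ended without resilient stressed 4 (adjusted p = 0.0807) and without the 4 larvae with intermediate copy shares (0.105).

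**Figure D3:**
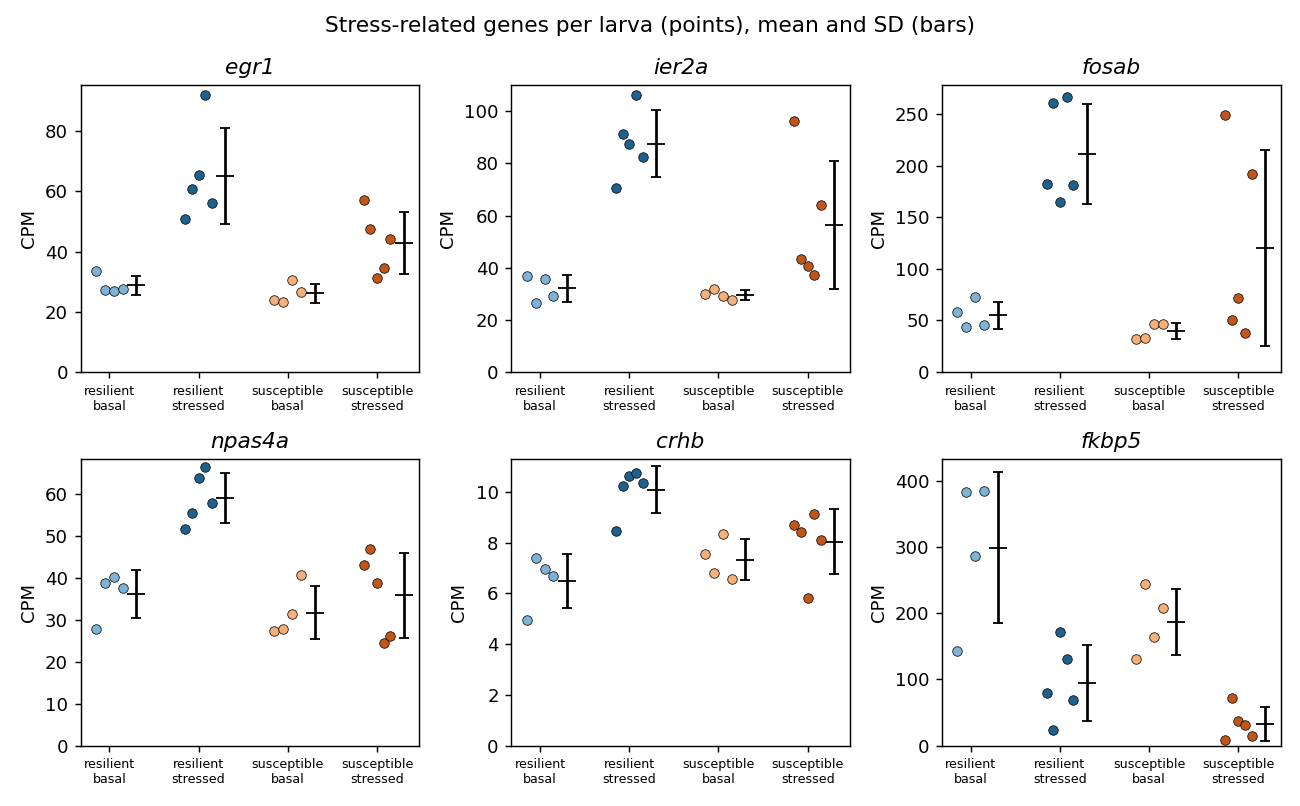
CPM (y axis, linear from 0) of 6 stress-related genes in each larva (points) of the 4 groups (x axis), with the group mean and SD as bars. egr1 averaged 65.04 CPM in resilient stressed and 42.9 CPM in susceptible stressed larvae, against 28.9 and 26.1 CPM in the corresponding basal larvae.

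In susceptible larvae no single gene passed the test for a stress response. Genes called numbered 0 with edgeR, 1642 had an unadjusted p below 0.05, and DESeq2 called 52. limma voom with sample quality weights called 0. Without susceptible stressed 2 edgeR called 13 genes, and without susceptible basal 1, without susceptible basal 1 and 2, without resilient stressed 4 or in a fit of these groups alone it called 1. Complement genes in susceptible larvae were not called as a list, with a list median of -0.12 (camera adjusted p = 0.0945, adjusted p = 0.846 with an estimated correlation). The list was called lower after stress without susceptible basal 3 (adjusted p = 0.000383), susceptible basal 4 (adjusted p = 0.00579), susceptible stressed 2 (adjusted p = 0.00347), susceptible stressed 3 (adjusted p = 0.039), the 4 larvae with intermediate copy shares (adjusted p = 0.00366) or with a block by title number (adjusted p = 0.0416). Without susceptible basal 1 and 2 it was called higher (adjusted p = 0.00273). c7a had log2 fold change 0.12, SE 0.18, adjusted p = 0.95 and c9 log2 fold change -0.13, SE 0.38, adjusted p = 0.982. Immediate early genes shifted upward as a list (camera adjusted p = 2.71e-05, adjusted p = 0.46 with an estimated correlation), and 8 of 33 members were higher adjusted over the list alone. That call ended without susceptible basal 1 and 2 (adjusted p = 0.264). Among the members egr1 had log2 fold change 0.72, SE 0.18, adjusted p = 0.301 and fosab log2 fold change 1.61, SE 0.47, adjusted p = 0.409 over all genes. fkbp5, a glucocorticoid-induced chaperone gene of the glucocorticoid receptor, was at 186 ± 49.8 CPM (n = 4) in basal and 32.9 ± 25.0 CPM (n = 5) in stressed larvae (-2.50, SE 0.58, adjusted p = 0.276). Among the genes not called with the smallest p were, upward, the retinal homeobox gene rx1 (0.71, SE 0.13, adjusted p = 0.216) and, downward, tsku (-0.44, SE 0.09, adjusted p = 0.25) and inhbaa (-0.77, SE 0.16, adjusted p = 0.25).

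Other lists moved in susceptible larvae, where 2 basal larvae stood apart. Erythrocyte list scores (mean centred log2 CPM) were 0.952 and 1.004 in susceptible basal 1 and 2 against 0.204 and -0.009 in susceptible basal 3 and 4, and slow muscle scores 0.700 and 0.523 against -0.062 and 0.073. Slow and cardiac muscle genes had a median of -0.44, with 22 of 26 members negative and 5 lower adjusted over the list alone (camera adjusted p = 1.03e-08, adjusted p = 0.103 with an estimated correlation). Oxidative stress and xenobiotic response genes had a median of -0.23 with 0 members called (camera adjusted p = 4.9e-07, adjusted p = 0.103 with an estimated correlation). Synapse and neuron markers had a median of 0.09 (camera adjusted p = 2.45e-06, adjusted p = 0.46 with an estimated correlation). Erythrocyte and heme genes were negative in 19 of 19 members, with a median of -0.54 (camera adjusted p = 1.57e-06, adjusted p = 0.46 with an estimated correlation). Without susceptible basal 1 and 2 the calls of the synapse and erythrocyte lists ended (adjusted p = 0.685 and 0.873), while the muscle and oxidative stress lists were called (0.0176 and 0.00273). On the muscle list susceptible stressed 4 scored -0.598. The other susceptible stressed larvae scored -0.168 to 0.102, a range that overlaps the 2 remaining basal larvae.

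Susceptible and resilient larvae were then compared after the stress. Some complement genes were higher in susceptible larvae, led by the anaphylatoxin receptor gene c5ar1 (1.66, SE 0.22, adjusted p = 0.00324), c7a (1.32, SE 0.18, adjusted p = 0.00324) and clu (0.57, SE 0.08, adjusted p = 0.00338). Of 39 list members 8 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 6.68e-14, adjusted p = 0.344 with an estimated correlation). c6, a gene of low level (0.409 ± 0.192 CPM in resilient and 1.25 ± 0.430 CPM in susceptible stressed larvae), was higher by 1.61 (SE 0.38) on the log2 scale (adjusted p = 0.0268), while c5 at 0.72 (SE 0.28), c9 at 1.12 (SE 0.36) and cfb at 1.04 (SE 0.38) did not pass the test (adjusted p = 0.16, 0.0938 and 0.138). Erythrocyte and heme genes were positive in 18 of 19 members with 0 called, with a median of 0.53 (camera adjusted p = 1.59e-05, adjusted p = 0.366 with an estimated correlation). Macrophage and microglia markers had 7 of 19 members higher (13 higher and 1 lower adjusted over the list alone), including havcr1 at 1.28 (SE 0.24) and lgals9l1 at 1.69 (SE 0.31) (camera adjusted p = 9.91e-08, adjusted p = 0.344 with an estimated correlation). Cell proliferation genes were positive in 43 of 43 members, of which 1 was called higher, and 5 were higher adjusted over the list alone, with a median of 0.58 (camera adjusted p = 1.7e-13, adjusted p = 0.372 with an estimated correlation; camera adjusted p = 0.000125 without resilient stressed 2 and 3, which stood apart on this list). The oxysterol receptor gene gpr183a (1.18, SE 0.18, adjusted p = 0.00527), hspb1 (1.28, SE 0.19, adjusted p = 0.00522), timp2b (1.27, SE 0.19, adjusted p = 0.00549) and socs3b (0.63, SE 0.11, adjusted p = 0.00781) were higher as well.

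Genes lower in susceptible than in resilient stressed larvae included pfkfb1 (-0.89, SE 0.11, adjusted p = 0.00159), the ubiquitin gene ubb, which has a numbered copy that makes its count uncertain (-1.11, SE 0.16, adjusted p = 0.0042) and zfand5b (-0.81, SE 0.11, adjusted p = 0.00324). They also included the slow muscle gene mybpc1 (-0.64, SE 0.09, adjusted p = 0.00347) and the glutathione-degrading enzyme gene chac1 (-1.02, SE 0.17, adjusted p = 0.00798). The iron hormone gene hamp was at 23.0 ± 16.2 CPM in resilient and 2.58 ± 2.71 CPM in susceptible stressed larvae (-3.10, SE 0.66, adjusted p = 0.0214). npas4a (-0.72, SE 0.17, adjusted p = 0.0293), fbxo32 (-1.32, SE 0.29, adjusted p = 0.0243) and the clock gene per1a (-1.09, SE 0.25, adjusted p = 0.0244) were lower, and egr1 at -0.60 (SE 0.16) did not pass the test (adjusted p = 0.0511). Enterocyte genes had 2 of 24 members lower (3 lower and 1 higher adjusted over the list alone), with vil1 at -0.84 (SE 0.16) and mep1a.1 at -0.63 (SE 0.17) (camera adjusted p = 0.00059, adjusted p = 0.344 with an estimated correlation).

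This comparison called 782 genes, 391 higher and 391 lower. Without resilient stressed larvae 2 and 3 the count was 16. With 1 surrogate variable it was 5, with a replicate block by title or bracket number 503 and 492, with an absolute log2 fold change of at least 1 132, with DESeq2 1538 and with voom 1504. Left out singly, resilient stressed 2 or 3 gave 237 and 197 genes, susceptible stressed 2, 3, 4 or 5 gave 510, 445, 259 and 515, and resilient stressed 5 gave 1730. The calls of c6 and fbxo32 ended without resilient stressed 2 or 3 or susceptible stressed 3 or 4 (adjusted p up to 0.0733), and that of hamp without resilient stressed 3 or susceptible stressed 4 (up to 0.0664). Without susceptible stressed 2 the value of hamp was -4.06. That of per1a ended without resilient stressed 1 or 3 or susceptible stressed 3 or 4 (up to 0.0826), and that of npas4a without resilient stressed 2, 3 or 4 or susceptible stressed 3, 4 or 5 (up to 0.0850). That of mep1a.1 ended without any single one of 11 larvae, among them 4 resilient stressed and all 5 susceptible stressed larvae (up to 0.119).

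Both comparisons used the same 5 resilient stressed larvae. Between them 264 genes were lower after stress in resilient larvae and higher in susceptible larvae after stress, against 14.0 expected of independent lists, and 239 moved the opposite way, against 10.8. The resilient stressed larvae were then divided so that no larva entered the group means of both comparisons. The 10 divisions gave 10 to 52 such genes (median 30.5), against 0.294 to 2.69 expected of independent lists. Each fit still held all larvae of the other groups, which set the spread of each gene for both comparisons. Genes of low spread can therefore be called in both, so the counts expected of independent lists are a reference only and no test. The 10 divisions also reuse the same larvae.

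**Figure D4:**
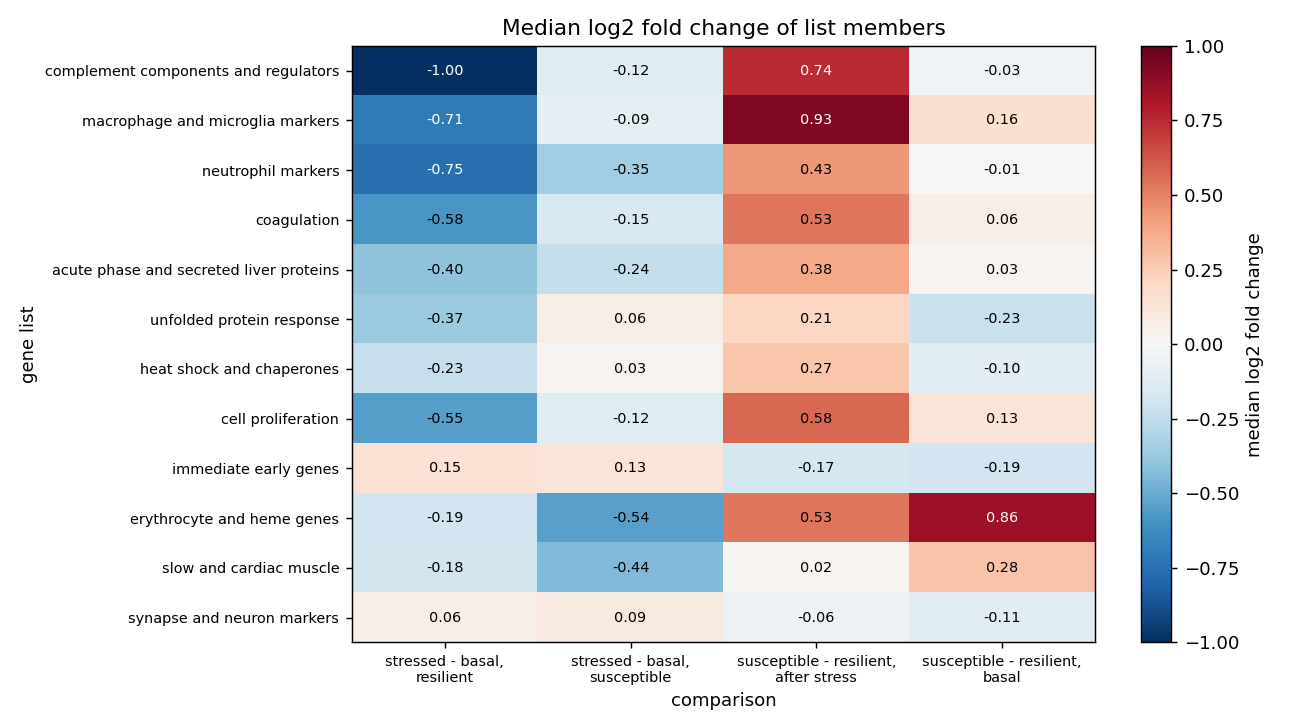
Median log2 fold change (colour and number) of the members of 12 gene lists (y axis) in the 4 comparisons of 2 groups (x axis). The complement list has a median of -0.995 after stress in resilient larvae and -0.12 in susceptible larvae.

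Before any stress no single gene passed the test between the archetypes. Genes called numbered 0 with edgeR, 1311 had an unadjusted p below 0.05, and DESeq2 called 10. limma voom with sample quality weights called 0. Without resilient basal 2 or resilient stressed 1 edgeR called 1 gene, and with a replicate block by bracket number 2. Complement genes had a median of -0.03 (camera adjusted p = 0.751, adjusted p = 0.948 with an estimated correlation), with c7a at -0.44 (SE 0.19), c3a.1 at -0.51 (SE 0.45) and c9 at -0.28 (SE 0.40) (adjusted p = 0.827, 0.932 and 0.969). The complement list was called lower in susceptible larvae without resilient basal 2 (adjusted p = 0.01), susceptible basal 2 (adjusted p = 0.0417) or susceptible basal 1 and 2 (adjusted p = 6.36e-07), and higher without resilient basal 1 and 3 (adjusted p = 0.00692), so its direction depends on the larvae. Erythrocyte and heme genes were positive in susceptible larvae in 19 of 19 members, and 13 were higher adjusted over the list alone, with a median of 0.86 (camera adjusted p = 1.89e-18, adjusted p = 0.238 with an estimated correlation). Synapse and neuron markers were negative in 35 of 40 members with a median of -0.11 (camera adjusted p = 2.56e-07, adjusted p = 0.452 with an estimated correlation). Immediate early genes were negative in 26 of 33 members before stress, with a median of -0.19 and 1 lower adjusted over the list alone (camera adjusted p = 3.55e-06, adjusted p = 0.452 with an estimated correlation). Unfolded protein response genes had a median of -0.23 with 0 members called (camera adjusted p = 3.55e-06, adjusted p = 0.452 with an estimated correlation). Without susceptible basal 1 and 2, which had high erythrocyte scores, the calls of the synapse and immediate early lists ended (adjusted p = 0.395 and 0.144), while the erythrocyte and unfolded protein lists were called in the same direction (4.7e-05 and 2.98e-08). The unfolded protein call ended without resilient basal 1 and 3, which had the highest scores of the basal larvae on that list (adjusted p = 0.483). Among the genes not called with the smallest p were tln2a (-0.52, SE 0.11, adjusted p = 0.627) and bpifcl (1.36, SE 0.31, adjusted p = 0.627).

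Whether the stress response itself differed between archetypes was tested as the susceptible response minus the resilient response. That difference was called for 31 genes, 15 positive and 16 negative. It equals the archetype difference after stress minus the basal one, so the basal larvae contribute to it. Each positive gene named below had a higher mean in resilient than in susceptible basal larvae, and each negative gene a lower one. For tln2a the basal difference was -0.52 and for c7a -0.44, neither of them called. Genes whose change was less negative or more positive in susceptible larvae included c7a (1.76, SE 0.26, adjusted p = 0.0127), c5ar1 (1.84, SE 0.32, adjusted p = 0.0404), il6st (0.70, SE 0.10, adjusted p = 0.0127) and stat3 (0.63, SE 0.12, adjusted p = 0.0459). They further included socs3b (1.01, SE 0.17, adjusted p = 0.0217), timp2b (1.88, SE 0.29, adjusted p = 0.0154) and tln2a (1.07, SE 0.15, adjusted p = 0.0117), as well as dysf (1.299, SE 0.20, adjusted p = 0.0127) and hspb1 (1.49, SE 0.28, adjusted p = 0.0459). The opposite held for pfkfb1 (-1.22, SE 0.16, adjusted p = 0.00666), asb10 (-1.52, SE 0.27, adjusted p = 0.0423) and the slow muscle genes tnnt1 (-1.18, SE 0.21, adjusted p = 0.0418) and mybpc1 (-0.77, SE 0.14, adjusted p = 0.0418). Complement genes had a median difference of 0.99, with 2 of 39 called and 6 adjusted over the list alone (camera adjusted p = 6.39e-11, adjusted p = 0.401 with an estimated correlation). For egr1 the difference was -0.45 (SE 0.25) and did not pass the test (adjusted p = 0.468). The count of 31 became 6 without resilient stressed 2 and 3 and 6 without resilient basal 1 and 3. It was 9 with 1 surrogate variable, 14 and 8 with a replicate block by title or bracket number, 52 with copies summed, 65 with voom and 402 with DESeq2. It became 9, 132 and 8 without resilient basal 1, 2 or 4, and 72, 11, 12, 14 and 76 without resilient stressed 1 to 5. It became 9, 119 and 5 without susceptible basal 1, 2 or 3, and 49, 10, 9 and 16 without susceptible stressed 2 to 5. Calls of il6st, tln2a, dysf and pfkfb1 held with any 1 larva left out. Those of c7a and timp2b ended without susceptible basal 3 (adjusted p = 0.05001 and 0.0533), and those of the other 7 genes named here ended without susceptible basal 3 and without further single larvae, 4 to 12 in all (up to 0.106). tln2a has a numbered copy, so its count is uncertain.

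Averaged over both archetypes, 334 genes were called between stressed and basal larvae, 145 higher and 189 lower in stressed larvae. These are different larvae of unknown clutch and day, so clutch or day cannot be separated from stress. egr1 (0.95, SE 0.13, adjusted p = 0.0127), ier2a (1.19, SE 0.16, adjusted p = 0.0127), fosab (1.77, SE 0.33, adjusted p = 0.0259) and foxq1a (1.46, SE 0.21, adjusted p = 0.0127) rose. The retinal homeobox gene rx1 (0.60, SE 0.09, adjusted p = 0.0127) rose as well. fkbp5 (-2.08, SE 0.41, adjusted p = 0.0296) and the clock repressor gene nr1d2a (-1.03, SE 0.19, adjusted p = 0.0237) fell. So did srgn (-1.11, SE 0.17, adjusted p = 0.0127), adamts1 (-0.80, SE 0.11, adjusted p = 0.0127) and the natriuretic peptide gene nppb (-2.54, SE 0.58, adjusted p = 0.0429). In resilient larvae alone fkbp5 was at -1.65 (SE 0.57) and did not pass the test (adjusted p = 0.0985). Without resilient stressed larvae 2 and 3 the count was 15, without susceptible basal 1 and 2 it was 43 and without resilient basal 1 and 3 it was 0. It was 0 and 4 with a replicate block by title or bracket number, 4 with 1 surrogate variable, 42 with an absolute log2 fold change of at least 1 and 987 with DESeq2. It became 76, 625, 86 and 193 without resilient basal 1 to 4, and 188, 68, 105, 532 and 679 without resilient stressed 1 to 5. It became 55 without susceptible basal 2, and 143, 141 and 85 without susceptible stressed 1, 3 or 5. The calls of fosab, fkbp5, nr1d2a and nppb ended without susceptible basal 2 and, except for nr1d2a, without further larvae (resilient basal 1 or resilient stressed 2 for fosab, resilient basal 3 or susceptible stressed 5 for fkbp5, 14 larvae in all for nppb; adjusted p up to 0.0953). Without susceptible basal 1 the value of nppb was -1.61.

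Averaged over both states, 5 genes differed between archetypes. tmem88a (0.68, SE 0.11, adjusted p = 0.0335) and gpr183a (0.82, SE 0.13, adjusted p = 0.0335) were higher in susceptible larvae. The glycogenin gene gyg1b (-0.63, SE 0.10, adjusted p = 0.0335) was lower, as was si:dkey-85k7.7, a clone-named gene that was chosen after its values were seen. Without resilient stressed larvae 2 and 3 the count was 0, without susceptible basal 1 and 2 it was 1 and without resilient basal 1 and 3 it was 8. It was 0 and 2 with a replicate block by title or bracket number, 0 with 1 surrogate variable or with an absolute log2 fold change of at least 1, 9 with voom and 169 with DESeq2. It became 8, 1, 3 and 1 without resilient basal 1 to 4, and 2, 1, 1, 3 and 15 without resilient stressed 1 to 5. It became 1, 0 and 1 without susceptible basal 2 to 4, and 1, 1, 2 and 1 without susceptible stressed 1, 3, 4 or 5. Each of the 3 calls named by symbol ended on leaving out any single one of 13 to 15 larvae (adjusted p up to 0.113).

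The authors' deposited table lists more genes at an adjusted p below 0.05. It has 1799 for resilient basal against stressed larvae and 1460 for resilient against susceptible stressed larvae. For resilient against susceptible basal larvae it has 19, and for susceptible basal against stressed larvae 49. Of the 1399 genes called here in the first of these comparisons, 1369 are among those of the authors' deposited table, and of the 782 called in the second, 773 are.

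Of 1971 pairs of a gene symbol and its numbered copy (a second row of the same symbol), 1395 had at least 20 reads in every larva. Among these, 19 pairs had larvae with a share of reads on the copy below 0.05 and others above 0.90. In resilient stressed larva 4 and susceptible basal larva 4, 57.9% and 47.4% of these pairs lay away from shares near 0, 0.5 and 1, against a median of 10.5% over the larvae, while resilient basal 4 and susceptible stressed 3 each had 26.3%. Without these 4 larvae the counts were 639 genes for the stress response of resilient larvae, 184 for the archetypes after stress, 0 for the difference of responses, 13 for the mean stress response, 2 for the mean archetype difference, and 0 for both remaining comparisons.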

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

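The tests of liver share, of resilient stressed larvae 2 and 3, of a separate clutch, of the copies, of the erythrocyte genes and of the complement genes at equal depth were chosen after the result was seen; the splits of the larvae and the equal-depth test over all genes were not.

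Within-group outliers were looked for in 132 sets of values by Dixon's ratio, and 5 stood out, where chance gives about 6.6. The unfolded protein response score of susceptible stressed 2 was 0.34, with the others of its group between -0.139 and -0.0433. egr1 in resilient basal 1 was at 33.6 CPM, with the others between 26.9 and 27.6. nr4a1 in resilient stressed 4 was at 9.77 CPM (others 3.21 to 4.60), pck1 in resilient stressed 3 at 975 CPM (others 373 to 530) and crhb in resilient stressed 1 at 8.46 CPM (others 10.21 to 10.7).

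The stress response differed between archetypes by a test of the difference for 31 genes. The values of this test also contain the basal difference between archetypes. On the log2 scale the difference was 1.07 for tln2a, 0.70 for il6st, 1.299 for dysf, 1.76 for c7a, 1.88 for timp2b, 1.01 for socs3b, 1.84 for c5ar1, 0.63 for stat3 and 1.49 for hspb1, and -1.22 for pfkfb1, -1.18 for tnnt1, -0.77 for mybpc1 and -1.52 for asb10.

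Other splits of the same larvae were fitted to ask whether chance can be excluded. For the archetypes after stress, 1 of 100 splits gave as many genes, the real one with 782 (highest other 488), and for the mean stress response 1 of 100 with 334 (highest other 9), so chance is excluded at the 0.05 level for both. For the mean stress response the splits exchanged stress states within each archetype, so what is excluded is no stress difference in either archetype. For the stress response of resilient larvae 2 of 100 splits reached 1399, the other calling 1520, and for the difference of responses 3 of 100 reached 31, the highest other calling 76; for the mean archetype difference 3 of 100 reached 5, the highest other calling 17. The share for the stress response of resilient larvae is under 0.05, so chance is excluded at that level there, although another split called more genes. For the difference of responses and the mean archetype difference, the splits exchanged archetypes within each state. That also broke up the archetype difference after stress, so these splits test for any archetype difference. Chance is therefore not excluded for these 2 comparisons themselves, and other splits called more genes than the real one. For the basal archetype comparison 35 of 35 splits reached the real count of 0 (highest other 48), and for the stress response of susceptible larvae 100 of 100 did (highest other 16), which every split must, so the splits decide nothing for these. The split with 1520 set resilient stressed 1 to 4 against resilient stressed 5 and the 4 basal larvae, so it is close to the real one. Splits that call 48 genes where the real one calls 0, or 17 where it calls 5, may point to a structure of the larvae beyond the groups, but whether they exceed chance was not tested.

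Complement genes were lower in resilient larvae after stress. A lower share of liver tissue would lower the other secreted liver genes by as much, but their median lay 0.596 above that of the complement genes on the log2 scale (95% bootstrap interval 0.160 to 1.04). The bootstrap drew genes, not larvae, and genes of a list move together (estimated correlation 0.431 for the complement list). Its interval therefore does not measure the spread between larvae and does not decide on liver share. Of 7 abundant liver genes 0 were called: fabp10a, fetub, rbp4 and serpina1 were at 0.26, 0.23, 0.07 and 0.06, while apoa1b, apoa2 and ttr were at -0.34, -0.585 and -0.242, so liver share stays open. Resilient stressed 2 and 3 do not carry the pattern alone, since without them the list median was -0.908, although only 2 of 39 members were then called. That test left out stressed larvae only. Resilient basal 1 and 3 had the highest scores of their group on this list (0.460 and 0.871), while resilient basal 2 scored -0.140. Without resilient basal 1 and 3 the list was called lower with the preset correlation, as given above. With every library thinned to the total of the smallest, the complement median was -1.077 with 15 of 38 tested members called, and 75.0% of all genes called at full depth were called. Thinning keeps the proportions within a library, so the median was bound to stay near its full-depth value. Most calls thus did not rest on the extra reads of the larger libraries, but a bias already present in the libraries could not be tested this way. A clutch of their own stays open: the mean difference of copy shares within the group was 0.3215 against 0.329 in random sets of 5 larvae, from 11 regions only, and in susceptible stressed larvae 0.2444 against 0.3285 (one-sided permutation test with 20000 random sets, p = 0.054), so clutch and group cannot be told apart, and a biological effect of archetype may hold as a hypothesis beside it.

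Copy shares lay between the modes in some libraries. Numbered copies may be 2 haplotypes of one locus, since shares of neighbouring pairs had a median absolute correlation of 0.985 against 0.081 for pairs on different chromosomes. With 1 pair per region, 6 of 11 regions lay between the modes in resilient stressed 4 and 7 in susceptible basal 4, against 2 in the median library, which is what RNA of more than 1 larva in resilient stressed 4 could give. Few regions bear on this, it was found and tested on the same libraries, and no biological explanation was tested.

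Erythrocyte genes were higher in susceptible basal larvae, where the mean list score exceeded that of resilient basal larvae by 0.803. Without susceptible basal 1 and 2 the difference was 0.362, between the bounds set for these 2 larvae alone and for all 4, so whether they alone carry it cannot be told apart with 2 larvae remaining. Without these 2 larvae the list was still called higher (camera adjusted p = 4.7e-05), but with the preset correlation of 0.01. The estimated correlation was 0.488, and with it the list was not called over all basal larvae (camera adjusted p = 0.238). The 2 remaining larvae scored 0.204 and -0.009, against -0.430 to -0.048 in resilient basal larvae. Among the separate stressed larvae the list was higher in susceptible ones (camera adjusted p = 1.59e-05, adjusted p = 0.366 with an estimated correlation). Without resilient stressed 2 and 3, which scored lowest on this list, camera adjusted p was 0.000524 there. A difference in blood between archetypes is thus only a hypothesis found on these larvae, which the list tests do not decide.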

How the results depend on the processing

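Leaving out resilient stressed 2 and 3, leaving out susceptible basal 1 and 2, leaving out resilient basal 1 and 3, leaving out the larvae with intermediate copy shares, and summing numbered copies were chosen only after the results were seen; the other alternatives were not. Of 105 gene and comparison values, those called numbered 21 after stress, 33 for stress in resilient, 13 for the difference, 10 for mean stress and 3 for mean archetype. Of these called values 0 changed direction in the alternatives run on them. A change of sign in a value not called was not counted. Values not called had no call to lose and are among those kept below. With RLE factors 105 kept their side of the threshold, with DESeq2 92 (10 others gained a call and the rest had no value), without resilient stressed 2 and 3 59 (46 lost it), and over all single omissions 72 (33 lost it). Summing numbered copies was run only on values of genes with such a copy, of which 10 kept their side and 1 gained a call. The cause of the moved counts below was not tested, except that leaving out larvae also leaves fewer samples.

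Genes called are given in the order archetypes basal (0), archetypes after stress (782), stress in resilient (1399), stress in susceptible (0), difference of responses (31), mean stress (334) and mean archetype (5), where the count moved by over 1.5 times. DESeq2 called 10 and 1538 for the archetypes, 52 for stress in susceptible, 402 for the difference, 987 for mean stress and 169 for mean archetype. voom called 1504 after stress, 65 for the difference and 9 for mean archetype. With 1 surrogate variable the counts were 5 after stress, 10 for stress in resilient, 9 for the difference, 4 for mean stress and 0 for mean archetype. A fit of only the groups compared called 640 for stress in resilient and 1 in susceptible. An absolute log2 fold change of at least 1 left 132 after stress, 284 for stress in resilient, 42 for mean stress and 0 for mean archetype. Without resilient stressed 2 and 3 the counts were 16, 69, 6, 15 and 0 (after stress, stress in resilient, difference, mean stress, mean archetype), and without the larvae with intermediate copy shares 184, 639, 0, 13 and 2. Without susceptible basal 1 and 2 the counts were 1 for stress in susceptible, 43 for mean stress and 1 for mean archetype. Without resilient basal 1 and 3 they were 38 for stress in resilient, 6 for the difference, 0 for mean stress and 8 for mean archetype, and 21 gene lists were called between the basal archetypes. Summing copies gave 52 for the difference. RLE and upper-quartile factors and both other low-count filters kept every count within 1.5 times.

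The replicate numbers do not pair the larvae: over 25 same-numbered pairs by title, correlations of deviations ran from -0.257 to 0.136, and over 19 by brackets from -0.124 to 0.195. With the title number as a replicate block 503 genes were called after stress, 863 for stress in resilient, 14 for the difference, 0 for mean stress and 0 for mean archetype; with the bracket number 2 were called basal, then 492, 430, 8, 4 and 2. The title block ended the calls of 27 named values and left 78 of the 105, values not called among them, on their side of the threshold.

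Leaving out 1 larva at a time gave 0 to 1, 197 to 1730, 398 to 1918, 0 to 13, 5 to 132, 55 to 679 and 0 to 15 genes in the order above. Gene lists called numbered 13, 24, 16, 15, 15, 19 and 14 in that order; over single omissions they ranged from 10 to 18, 20 to 24, 13 to 20, 12 to 21, 13 to 18, 16 to 20 and 13 to 19. With an estimated correlation 0 lists were called in every comparison, and fry called 0, 8, 6, 2, 0, 0 and 5. Small effects were recovered less often: of simulated changes of 0.5 on the log2 scale, 35.8% were recovered for stress in resilient larvae, the highest share of the 5 comparisons simulated, and 8.96% for the difference of responses, the lowest. The simulated genes were drawn independently, so these shares may be too high for the real larvae.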

Other observations

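The lists named here were picked for mention after their values had been seen. Some lists not described above moved with camera's preset correlation and with few or no single calls. Cytosolic ribosomal protein genes were positive in 68 of 69 members in resilient larvae after stress, with a median log2 fold change of 0.14 (camera adjusted p = 1.82e-11, adjusted p = 0.647 with an estimated correlation). Exocrine pancreas digestive enzymes were negative in 23 of 23 members in susceptible against resilient stressed larvae, with a median of -0.82 and 1 member called (camera adjusted p = 1.44e-05, adjusted p = 0.431 with an estimated correlation). Ionocyte genes had a median of -0.22 in susceptible larvae after stress (camera adjusted p = 0.000476, adjusted p = 0.46 with an estimated correlation), with 0 members called. Enterocyte genes had a median of -0.32 there (camera adjusted p = 6.02e-06, adjusted p = 0.187 with an estimated correlation).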
